A study of Mus musculus with 4 samples.

How the data were processed

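Poly(A)-selected RNA of primary mouse embryonic fibroblasts was sequenced in 4 libraries, 1 per genotype, per the labels' protocols. The labels gave the genotypes as wild type, Gadd45-deficient, third-generation (G3) Terc-deficient and G3 deficient for both, all on the C57BL/6 strain, and the series' design text named the first gene as Gadd45a. RNA was treated with DNase, selected on oligo(dT) beads, sheared, and copied into cDNA with random hexamers, per the labels' protocols.

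The authors deposited FPKM values, fragments per kilobase of transcript scaled to the number of mapped fragments, with 1 value per gene symbol in each library, and the unit was read from the deposited tables. TopHat2 2.1.1, Cufflinks 2.2.1 and the mouse build mm9 were named in the submitters' processing notes, without their roles. The gene annotation, the strand setting and any filters were not given in the sources used here. FPKM divides each value by the library's mapped fragments, so a few very abundant transcripts in a library lower all its other values slightly. It also gives 1 value per gene, so exons and isoforms could not be looked at separately. Cufflinks divides fragments that match several gene copies, so values of genes with near-identical copies are uncertain, as are values of overlapping and antisense genes where strand was not used.

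Each table listed 23235 symbols, each on 1 line. Symbols of short non-coding RNA, numbering 738, were left out because FPKM is unreliable for genes shorter than a fragment, and 22497 symbols were compared. Of these, 20140 (89.5%) carried a name found in GENCODE release M21, an annotation of the build GRCm38. Because that build differs from the files' build, no coordinates were used from it beyond which genes neighbour each other, which lie on the X or Y chromosome, transcript lengths and distances to chromosome ends. Symbols in the gene lists were matched through current names and synonyms.

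The tables gave no read totals. Depth was estimated from low values, which lie at whole multiples of what 1 fragment is worth for a gene's length. Genes with transcripts of 1500 to 8000 nt and FPKM up to 0.05 were used, with a fragment length of 200 nt. The estimates were 19500000 fragments for wild type, 19900000 for the library labelled Gadd45a-deficient, 19700000 for the library labelled G3 Terc-deficient and 19900000 for the library labelled G3 doubly deficient. Between 75% and 82.6% of the low values lay within 0.1 of a whole fragment. Each estimate was set at the commonest of these same values, so the share is no independent check of it. At these depths an FPKM of 1 on a 2 kb transcript stands for about 39.5 fragments. Median-of-ratios size factors lay between 0.976 and 1.02, so the libraries were close to a common scale.

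For each gene the difference of log2(FPKM + 1) was taken between the libraries of 5 comparisons, with a pseudocount of 1 FPKM that makes differences of low genes smaller than their true ratios. A gene was counted as higher or lower when the difference was at least 1 or at most -1, a 2-fold difference of FPKM + 1. No test, error or p-value was computed, since no genotype had a second library, and every difference is one between single libraries without a replicate check. Treating the labels as additive would have left 1 residual degree of freedom, and such a model was not fitted. A double difference subtracted the Gadd45a comparison in Terc-proficient cells from that in G3 cells. Pearson's r across the 11589 genes with a mean FPKM of 1 or more compared pairs of differences. The r that a shared library produces when all libraries are alike in spread came from 100 permutations of the 4 library values within each gene.

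Before the data were examined, 24 gene lists, 13 lists of cell type markers and 3 lists of genes by position (within 5 Mb of a distal chromosome end, of Gadd45a or of Terc) were fixed. All 3 position lists were restricted to protein-coding genes. Members with a mean FPKM of 1 or more were measured. The median difference of each list with at least 3 measured members was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. A list is said to stand apart when its percentile was under 2.5 or over 97.5, which describes these libraries only. Random lists would put 1.2 of 24 lists apart, but they hold unrelated genes, and without replicate cultures it could not be measured how often lists of 1 pathway stand apart between cultures of 1 genotype. The genes named are Gadd45a, Terc, Tert, Gadd45b and Gadd45g, the 10 largest differences each way in the first 3 comparisons and the 5 largest each way in the others, and up to 4 members with the largest difference from each list that stands apart, and from the p53 and telomere lists in any case. Some results that this rule selects are not reported here. A gene named outside this rule is said to be chosen after its values were seen.

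The procedure was tested on simulated libraries of 22497 genes made from the comparison of the libraries labelled G3 Terc-deficient and wild type, with 200 genes changed and noise with an SD of 0.15 on the log2 scale. Between it and the library standing for wild type, all genes changed by 1.5 or 3 on the log2 scale passed the size rule (100%) and 0% of unchanged genes did. Between the libraries standing for Gadd45a-deficient and wild type, where no gene was changed, 3% of 200 unchanged lists stood apart. This checks the scripts, and says nothing about variation between cultures, which was not simulated.

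Alternatives fixed before the data were examined were a pseudocount of 0.1 FPKM, a minimum mean FPKM of 5 (10 for the correlations), median-of-ratios rescaling, quantile normalization, rescaling of each library to a sum of 1000000 (which also makes all values larger against the pseudocount), keeping short RNA, 10 expression bins, 2 Mb windows and Spearman's rho. The minimum mean FPKM for list members was applied anew to the values of each alternative, so a list's measured members can differ between them. Leaving out X and Y genes, and leaving out genes listed at 0 in any library, were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.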

Results

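Gene expression was measured by RNA sequencing in primary fibroblasts grown from mouse embryos. Telomerase needs the RNA template encoded by Terc, and mice bred without it for 3 generations (G3) carry shortened telomeres. Gadd45a encodes a stress-induced protein linked to DNA repair and demethylation. The design asks what loss of Gadd45a does in cells with and without telomerase RNA, and what G3 Terc deficiency does with and without Gadd45a. There was 1 library for each of the 4 genotypes, with an estimated depth of 19500000 to 19900000 fragments, so differences below are between single cultures and have no replicate check. Values are FPKM as deposited, and differences are on the log2(FPKM + 1) scale.

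The Gadd45a transcript went against the labels. It stood at 22.9 FPKM in the library labelled wild type, 33.9 in the library labelled Gadd45a-deficient, 31.4 in the library labelled G3 Terc-deficient and 45.1 in the library labelled G3 doubly deficient. It was thus 1.48-fold higher, not lower, in the library labelled Gadd45a-deficient than in wild type, and 1.43-fold higher in the library labelled G3 doubly deficient than in the library labelled G3 Terc-deficient. A single value per gene does not show which exons the fragments came from, so the targeted part of the gene could not be looked at. Genotypes are therefore given as labelled throughout. Terc was listed at 0.53 FPKM in wild type, 0.26 in the library labelled Gadd45a-deficient and 0 in both G3 libraries. Counted over the full 397 nt of Terc, the values above 0 stand for about 4.10 and 2.05 fragments. They follow the labels, but 3 fragments on Terc, the floor used here, correspond to 0.38 to 0.39 FPKM at full length. With the fragment length of 200 nt taken off, as for the depth estimate, the counts would be smaller and the floor would lie above the wild-type value. The difference was thus hardly detectable at this depth in poly(A)-selected RNA. Tert, the reverse transcriptase of telomerase, stood at 1.21, 1.12, 2.23 and 2.01 FPKM in the same order. The related genes Gadd45b (26.6, 28.4, 28.8 and 25 FPKM) and Gadd45g (118, 147, 131 and 118 FPKM) differed little between libraries.

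Sex-linked transcripts separated the library labelled Gadd45a-deficient from the others. It held the Y-linked genes Ddx3y (16.4 FPKM), Eif2s3y (23.1 FPKM), Kdm5d (4.34 FPKM) and Uty (3.21 FPKM) with Xist at 0.15 FPKM, while the other 3 libraries held Xist, the RNA of the inactive X chromosome, at 24.0 to 34.1 FPKM and Ddx3y at 0.023 FPKM or less. Sex therefore differed along with genotype in both comparisons that use this library. In the list of sex-linked genes 3 of 4 measured members were higher and 1 lower than in wild type, with a median difference of 3.25. The list pools Xist with Y-linked genes that differed in the opposite direction. The side of its median therefore shows only that Y-linked members outnumber Xist.

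**Figure D1:**
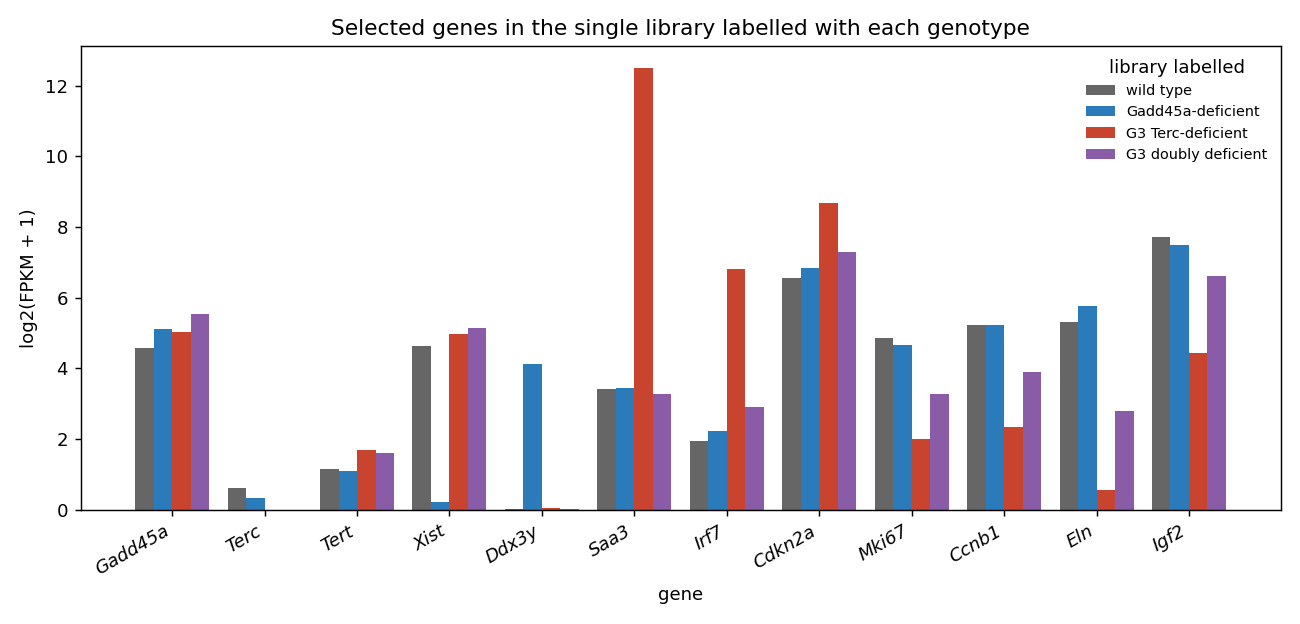
Expression of 12 genes on the log2(FPKM + 1) scale, with 1 bar per library and colours for the labelled genotype, so no error can be drawn. Gadd45a is lowest in wild type (22.9 FPKM), Saa3 reaches 5800 FPKM in the library labelled G3 Terc-deficient alone, and Mki67 and Ccnb1 are lower in both G3 libraries.

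The library labelled Gadd45a-deficient closely resembled wild type, with r = 0.99 across genes. Only 40 genes were higher and 31 lower by the size rule. Besides the sex-linked genes, the higher ones included Il1rn, the interleukin-1 receptor antagonist (4.44 and 17.4 FPKM in wild type and the library labelled Gadd45a-deficient), and Coch, an extracellular matrix protein (4.72 and 15.6 FPKM). The lower ones included Alb, serum albumin (5.40 and 0.027 FPKM), the lens crystallin Cryaa (6.11 FPKM and listed at 0), the interferon-inducible gene Ifi202b (4.79 FPKM and listed at 0), and Hoxc12 (5.93 and 0.63 FPKM), a patterning gene of posterior body regions. Alb, Cryaa and Ifi202b were also at 0.33 FPKM or less in both G3 libraries, so that wild type stood apart for them. Gadd45a was not lower in the library labelled Gadd45a-deficient, so none of these differences can be tied to its loss from these values.

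The remaining named genes of this comparison were poorly characterised or of several copies. LOC100861572 (listed at 0 in wild type, 164 FPKM in the library labelled Gadd45a-deficient), LOC100861570 (336 FPKM and listed at 0) and LOC100302567 (37.3 FPKM and listed at 0) led the list, and their values, at 0 in some libraries and high in others, are uncertain. Ndufs5 (3.74 and 16.7 FPKM) and Rpl26 (3.39 and 14.1 FPKM) have processed copies elsewhere in the genome and are uncertain. The transcript 2400009B08Rik (0.34 and 2.66 FPKM) was higher, and E230016M11Rik (4.57 and 0.032 FPKM), Gm7334 (6.98 and 0.81 FPKM) and the pseudogene Pisd-ps1 (4.68 and 0.63 FPKM), whose value is uncertain, were lower. Of the 71 genes past the rule, 14 were listed at 0 in 1 of the libraries, which in such tables can be a failed estimate. With a pseudocount of 0.1 FPKM 372 genes were higher and 447 lower, since the rule then reaches genes of a few fragments.

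Among the lists, 14 of 24 stood apart between these libraries although no median but that of the sex-linked genes went beyond 0.27 in size. Interferon-stimulated genes had a median of 0.27 with none of 27 past the size rule, led by Ifi27l1 (46.3 and 90.7 FPKM) and Bst2 (59.1 and 109 FPKM). Senescence inhibitors and secretory genes had a median of 0.22, where Cxcl5 (9.42 and 18.9 FPKM) and Cxcl1 (2.75 and 5.58 FPKM) were higher and Igfbp5 (470 and 223 FPKM) was lower. Contractile genes (0.22, with Cnn1 at 73.1 and 120 FPKM and, in the opposite direction, desmin, Des, at 25.9 and 12.9 FPKM), collagen and matrix genes (0.13), NRF2 antioxidant genes (0.14) and glycolysis and hypoxia genes (0.096) also stood apart as higher. ATF4 and unfolded protein response genes (-0.23, with Trib3 at 70.2 and 41.5 FPKM), cholesterol synthesis genes (-0.21), posterior Hox genes (-0.20), DNA damage response genes (-0.12), ribosomal protein genes (-0.12), heterochromatin genes (-0.11) and oxidative phosphorylation genes (-0.087) stood apart as lower. Lists that did not stand apart were p53 targets (-0.054, none of 30 past the rule, the largest difference being Fas at 3.29 and 5.18 FPKM), G1/S and replication genes (-0.035), mitotic genes (-0.064), telomere maintenance genes (-0.060), base excision repair and DNA methylation genes (-0.085), immediate early genes (-0.046), histone genes (0.0081), imprinted genes (-0.039), Wnt targets (0.027) and anterior Hox genes (0.043). Without replicate cultures it is not known how large such shifts are between cultures of 1 genotype.

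The library labelled G3 Terc-deficient differed far more from wild type, with r = 0.89 across genes, 1282 genes higher and 749 lower. With a pseudocount of 0.1 FPKM the counts were 2705 and 1440. Saa3, an acute-phase serum amyloid with the largest difference, stood at 9.55 FPKM in wild type and 5800 FPKM in the library labelled G3 Terc-deficient, a 607-fold difference. The eosinophil chemokine Ccl11 stood at 0.47 and 298 FPKM, the iron-scavenging lipocalin Lcn2 at 0.63 and 175 FPKM, the neutrophil chemokines Cxcl1 and Cxcl5 at 2.75 and 189 FPKM and at 9.42 and 440 FPKM, complement C3 at 0.45 and 56.3 FPKM, and the matrix protease Mmp3 at 2.41 and 116 FPKM. Prl2c3, a proliferin, was listed at 0 in wild type and at 38.6 FPKM, and the peptide hormone gene Cck stood at 24.9 and 914 FPKM. The uncertain LOC100861572 was listed at 0 and at 166 FPKM.

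All 27 measured interferon-stimulated genes were higher by the size rule, with a median difference of 3.09. Irf7, a transcription factor of the interferon response, stood at 2.88 and 110 FPKM in wild type and the library labelled G3 Terc-deficient, Ifi44 at 0.27 and 35.9 FPKM, Oasl2 at 1.08 and 45.9 FPKM and Usp18 at 2.22 and 69.6 FPKM. Among senescence inhibitors and secretory genes 17 of 21 were higher and 1 lower, with a median of 2.80. Ccl8 (1.83 and 81.5 FPKM) was among the higher ones, and Igfbp5 (470 and 22 FPKM) was the lower one. Cdkn2a, which encodes the cell cycle inhibitors p16 and p19 (ARF), stood at 93.9 and 407 FPKM, a 4.33-fold difference. It was chosen after its values were seen, as was Cdkn1a, the p53-induced inhibitor p21, at 236 and 452 FPKM. Of 30 p53 targets 7 were higher and none lower, with a median of 0.46. The death receptor Fas (3.29 and 41.1 FPKM), Perp (1.63 and 18.4 FPKM), Gdf15 (3.84 and 28 FPKM) and Dcxr (25.7 and 93.8 FPKM) led them.

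Proliferation genes lay in the opposite direction. All 27 mitotic genes were lower by the size rule, with a median of -2.20. The proliferation marker Mki67 stood at 27.9 and 2.97 FPKM, the mitotic cyclin Ccnb1 at 36.5 and 4.06 FPKM, the kinase Plk1 at 33.2 and 4.39 FPKM and survivin, Birc5, at 55.6 and 8.03 FPKM. Of 26 G1/S and replication genes 20 were lower and none higher, with a median of -1.67, among them Uhrf1 (26.4 and 4.35 FPKM), Gins1 (10.6 and 1.38 FPKM) and the replicative helicase subunits Mcm5 (23 and 3.95 FPKM) and Mcm3 (31.5 and 5.76 FPKM). DNA damage response genes had a median of -0.45 with 6 of 24 lower, among them Chek1 (3.32 and 0.65 FPKM), Nbn (11.7 and 4.25 FPKM) and H2afx (48.0 and 19.5 FPKM). Base excision repair and DNA methylation genes had a median of -0.43 with 6 of 22 lower, among them Lig1 (18.9 and 5.70 FPKM), Fen1 (18.4 and 5.70 FPKM), Ung (4.20 and 0.89 FPKM) and the maintenance methyltransferase Dnmt1 (32.7 and 13.2 FPKM). Heterochromatin genes had a median of -0.36 with 3 of 17 lower, namely the histone methyltransferase Suv39h1 (13.9 and 4.52 FPKM), Cbx5, encoding HP1 alpha (26.4 and 9.47 FPKM), and the deacetylase Sirt1 (5.46 and 1.88 FPKM). The telomere maintenance list did not stand apart (median -0.21, 3 of 19 lower). Its lower members were Dkc1 (17.0 and 6.14 FPKM) and Nhp2 (72.2 and 33.3 FPKM) of the telomerase and small nucleolar RNA complexes and the helicase Rtel1 (7.34 and 2.89 FPKM), while the shelterin gene Terf1 stood at 9.03 and 4.18 FPKM.

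Metabolic lists also separated these libraries. Glycolysis and hypoxia genes had a median of 1.03 with 11 of 20 higher, among them Bnip3 (12.1 and 142 FPKM), Egln3 (2.78 and 26.6 FPKM), P4ha2 (54.3 and 233 FPKM) and Pdk1 (3.20 and 15.4 FPKM). NRF2 antioxidant genes had a median of 1.01 with 6 of 11 higher and 1 lower, with Nqo1 at 8.24 and 51.9 FPKM and the haem oxygenase Hmox1 at 83.0 and 410 FPKM. Cholesterol synthesis genes had a median of -1.40 with 13 of 17 lower, led by Insig1 (99.7 and 25.1 FPKM) and Lss (63.8 and 16.2 FPKM). ATF4 and unfolded protein response genes had a median of -0.83 with 8 of 19 lower, led by Trib3 (70.2 and 9.60 FPKM), the amino acid transporter Slc7a5 (120 and 17.4 FPKM) and the serine synthesis genes Psat1 (178 and 44.4 FPKM) and Phgdh (230 and 57.6 FPKM). Ribosomal protein genes had a median of -0.51 with none of 26 past the rule. Replication-dependent histone genes, measured as polyadenylated forms, had a median of 1.39 with 5 of 7 higher, with Hist1h4h at 2.43 and 43.1 FPKM and Hist1h1c at 44.1 and 222 FPKM.

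Elastin, Eln, stood at 38.9 and 0.47 FPKM in wild type and the library labelled G3 Terc-deficient, the fibrillin Fbn2 at 70.1 and 5.06 FPKM, the R-spondin receptor Lgr5 at 34.6 and 1.41 FPKM, Tnnt2 at 23.2 and 0.78 FPKM, Cmklr1 at 13.5 and 0.17 FPKM, Gfra1 at 32.7 and 1.93 FPKM and the connexin Gjb2 at 11.0 and 0.069 FPKM. Imprinted genes had a median of -0.46 with 6 of 18 lower and 1 higher. Mest (27.4 and 1.27 FPKM), the growth factor Igf2 (209 and 20.7 FPKM), H19 (389 and 73.8 FPKM) and Slc38a4 (19 and 5.63 FPKM) had the largest differences. Collagen and matrix genes (median -0.36, 6 of 24 lower and 3 higher), contractile genes (0.17), immediate early genes (0.15), Wnt targets (0.18), anterior Hox genes (0.37), posterior Hox genes (0.32) and oxidative phosphorylation genes (-0.28) did not stand apart, nor did sex-linked genes (0.052).

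**Figure D2:**
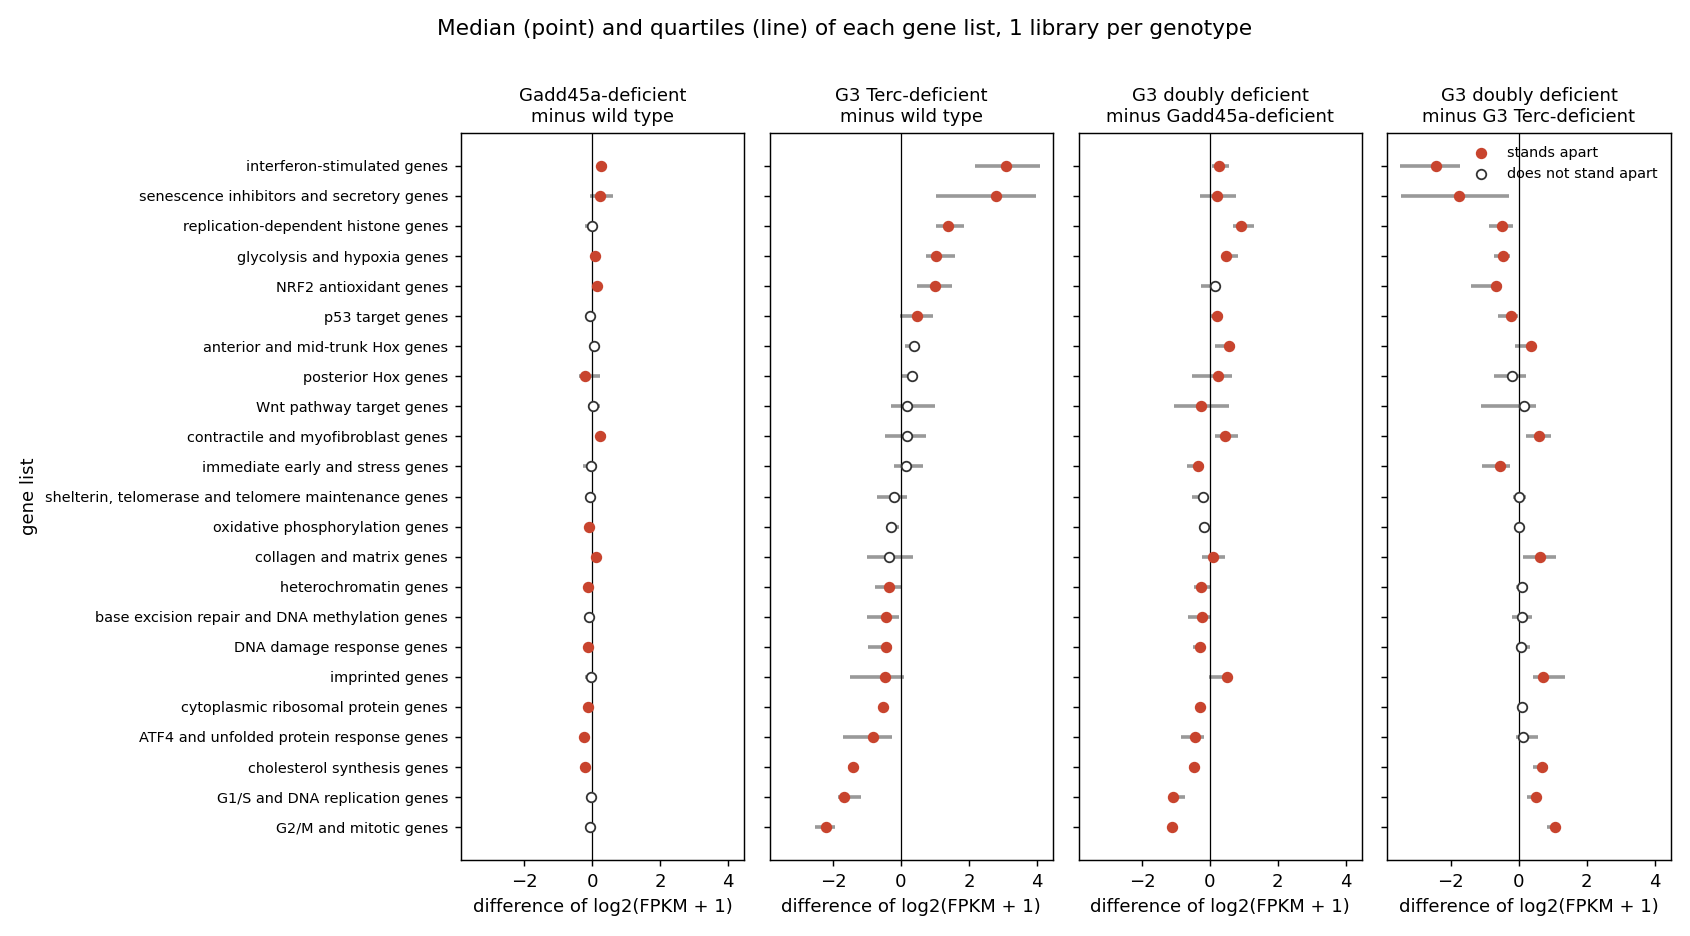
Medians (points) and quartiles (lines) of the difference of log2(FPKM + 1) over the measured members of each gene list, except the sex-linked list, in 4 comparisons between single libraries, with filled points for lists that stand apart from random lists. Interferon-stimulated genes have medians of 0.27, 3.09, 0.28 and -2.45 from left to right, and mitotic genes -0.064, -2.20, -1.12 and 1.07.

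The question that joins the mutations, what the label Gadd45a-deficient goes with in G3 Terc-deficient cells, is addressed by the difference between the G3 libraries. In the library labelled G3 doubly deficient 191 genes were higher and 628 lower than in the library labelled G3 Terc-deficient, with interferon-stimulated and secretory genes lower and mitotic genes higher. Saa3 stood at 8.73 FPKM against 5800 FPKM, Lcn2 at 0.39 against 175 FPKM, Ccl11 at 1.90 against 298 FPKM, the chemokine Ccl20 at 0.42 against 51.9 FPKM, Cxcl1 at 4.10 against 189 FPKM, Cxcl5 at 14.9 against 440 FPKM, Mmp3 at 2.67 against 116 FPKM and C3 at 0.87 against 56.3 FPKM. Of 27 interferon-stimulated genes 25 were lower and none higher, with a median of -2.45, among them Cxcl10 (0.95 against 32.5 FPKM), Irf7 (6.46 against 110 FPKM), Ifi44 (1.74 against 35.9 FPKM) and Isg15 (20.3 against 268 FPKM). Senescence inhibitors and secretory genes had a median of -1.74 with 13 of 21 lower and 1 higher, with Ccl2 at 93.0 against 1638 FPKM. Gadd45a itself stood higher in the library labelled doubly deficient, so these directions belong to the labels, not to a measured loss of the transcript. Quantile normalization gave 290 higher and 547 lower genes, and a pseudocount of 0.1 FPKM 732 and 1624.

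All 27 mitotic genes had a positive difference between the G3 libraries and 15 passed the size rule, with a median of 1.07. Ccnb1 stood at 14.0 FPKM in the library labelled G3 doubly deficient against 4.06 FPKM, Plk1 at 14.6 against 4.39 FPKM, Cdc20 at 28 against 9.14 FPKM and the centromeric histone Cenpa at 14.2 against 4.56 FPKM. These values remained below those of wild type (36.5, 33.2, 62.5 and 32.0 FPKM). G1/S and replication genes had a median of 0.50 with none of 26 past the rule, with Mcm5 at 8.75 against 3.95 FPKM and Tk1 at 14.8 against 7.22 FPKM. Of 30 p53 targets 5 were lower and none higher, with a median of -0.24, among them Perp (2.33 against 18.4 FPKM), Fas (7.86 against 41.1 FPKM), Gdf15 (7.52 against 28 FPKM) and Plk2 (101 against 241 FPKM). The chosen genes Cdkn1a and Cdkn2a stood at 280 against 452 FPKM and at 156 against 407 FPKM.

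The heparin-binding growth factor Ptn stood at 333 FPKM in the library labelled G3 doubly deficient against 26.1 FPKM, the tendon gene Tnmd at 86.6 against 6.56 FPKM, Nov at 42.6 against 3.38 FPKM, Mgp, an inhibitor of calcification, at 556 against 93.8 FPKM, Il1rn at 14.2 against 0.47 FPKM, Gjb2 at 8.59 against 0.069 FPKM, 1500015O10Rik at 56.0 against 5.93 FPKM, Sema7a at 15.1 against 1.32 FPKM and the pseudogene Pisd-ps3 at 11.6 against 0.063 FPKM. Pisd-ps3 and the related pseudogene Pisd-ps1 (19.9 against 40.4 FPKM) differed in opposite directions, so fragments may have been divided between them, and both values are uncertain. Collagen and matrix genes had a median of 0.62 with 7 of 24 higher and 2 lower. Eln (5.95 against 0.47 FPKM) and Col6a3 (177 against 39.4 FPKM) were higher and the small proteoglycans Dcn (67.0 against 584 FPKM) and Lum (5.49 against 42.6 FPKM) lower. Contractile genes had a median of 0.60 with 4 of 15 higher, namely Actg2 (504 against 108 FPKM), Cnn1 (357 against 132 FPKM), Tpm2 (423 against 196 FPKM) and smooth muscle actin, Acta2 (3946 against 1913 FPKM). Imprinted genes had a median of 0.71 with 6 of 18 higher and none lower, led by H19 (475 against 73.8 FPKM), Mest (11.3 against 1.27 FPKM), Igf2 (96.7 against 20.7 FPKM) and Plagl1 (14.1 against 2.92 FPKM).

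Cholesterol synthesis genes had a median of 0.68 with 1 of 17 higher, Insig1 (56.1 against 25.1 FPKM), and anterior Hox genes a median of 0.37 with none of 19 past the rule. NRF2 antioxidant genes (-0.66, 5 of 11 lower, with Nqo1 at 13 against 51.9 FPKM), immediate early genes (-0.56, 6 of 19 lower, with Ier3 at 43.4 against 252 FPKM and Egr1 at 21.8 against 72.8 FPKM), glycolysis and hypoxia genes (-0.45, 1 of 20 lower, Egln3 at 7.32 against 26.6 FPKM) and histone genes (-0.49, 2 of 7 lower) stood apart as lower. Telomere maintenance genes (0.015, none of 19 past the rule, with Nhp2 at 53.3 against 33.3 FPKM), DNA damage response genes (0.081), base excision repair genes (0.088), heterochromatin genes (0.095), ribosomal protein genes (0.097), ATF4 and unfolded protein response genes (0.12), posterior Hox genes (-0.19) and Wnt targets (0.15) did not stand apart. Oxidative phosphorylation genes had a median of -0.0043 and sex-linked genes of 0.0054. Rps27 stood at 9.70 against 448 FPKM, but this ribosomal protein has near-identical copies among which fragments can be divided, and its value is uncertain. LOC100302567, of unknown nature, was listed at 0 against 36.9 FPKM.

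Between the libraries labelled G3 doubly deficient and Gadd45a-deficient, which differ in the Terc label and in sex-linked transcripts, proliferation genes were again lower and hypoxia genes higher. There were 300 genes higher and 293 lower, against 1241 and 792 with a pseudocount of 0.1 FPKM and 538 and 380 with each library rescaled to a sum of 1000000. Mitotic genes had a median of -1.12 with 22 of 27 lower, among them Mki67 (8.69 FPKM in the library labelled G3 doubly deficient against 24.1 FPKM) and Birc5 (18.9 against 49.5 FPKM), and G1/S genes a median of -1.08 with 16 of 26 lower, led by Mcm3 (9.75 against 30.4 FPKM). Glycolysis and hypoxia genes had a median of 0.47 with 5 of 20 higher, led by Bnip3 (71.3 against 15.2 FPKM). Interferon-stimulated genes also stood apart as higher, with a median of 0.28 and none of 27 past the rule, as did senescence inhibitors and secretory genes, with a median of 0.20 (-0.012 when each library was rescaled to a sum of 1000000) and 3 of 21 higher and 1 lower. The higher ones were the growth factor Hgf (12.6 against 3.02 FPKM), Mmp10 (3.88 against 0.83 FPKM) and Igfbp3 (77.5 against 33.1 FPKM), and the lower one Igfbp5 (18.5 against 223 FPKM). The p53 targets stood apart as higher with a median of 0.20 and none of 30 past the rule, Dcxr (49.5 against 24.9 FPKM) and Ak1 (135 against 73.8 FPKM) having the largest differences. Of the telomere maintenance genes (-0.20) Dkc1 alone passed the rule, at 8.14 against 17.3 FPKM.

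The largest single differences in that comparison were Xist, with the Y-linked genes Eif2s3y and Ddx3y in the opposite direction, the Wnt antagonist Sfrp1 (189 against 14.7 FPKM), Hoxc12 (12.9 against 0.63 FPKM), the histone gene Hist1h4m (9.47 against 0.25 FPKM), the uncertain Pisd-ps1 (19.9 against 0.63 FPKM), and, lower, Igfbp5, the tenascin Tnn (0.32 against 12.9 FPKM) and the uncertain Rps27 (9.70 against 220 FPKM). Histone genes (0.91, 3 of 7 higher), anterior Hox genes (0.58, 3 of 19 higher, with Hoxa5 at 10.3 against 2.12 FPKM), imprinted genes (0.51, with Meg3 at 331 against 136 FPKM higher and Mest at 11.3 against 27.4 FPKM lower), contractile genes (0.44, 3 of 15 higher, with Myh11 at 52.1 against 9.48 FPKM), posterior Hox genes (0.25, 4 of 18 higher and 3 lower, with Hoxd13 at 0.20 against 8.66 FPKM) and collagen and matrix genes (0.11, though with 2 of 24 higher and 3 lower) stood apart as higher, beside smooth muscle and pericyte markers (0.64, 3 of 6 higher and 1 lower, or -0.099 with a mean FPKM of at least 5). Cholesterol synthesis genes (-0.46), ATF4 and unfolded protein response genes (-0.42), immediate early genes (-0.34, with Myc at 14.9 against 36.4 FPKM), DNA damage response genes (-0.30), ribosomal protein genes (-0.29), Wnt targets (-0.27, though with 3 of 11 higher and 3 lower, Sfrp1 and Lgr5, at 4.76 against 33.6 FPKM, among them), heterochromatin genes (-0.26) and base excision repair genes (-0.22) stood apart as lower. Sex-linked genes (-3.25) also stood apart, with 3 of 4 measured members lower and Xist higher. NRF2 antioxidant genes (0.15) and oxidative phosphorylation genes (-0.17) did not.

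Against wild type, 455 genes were higher and 351 lower in the library labelled G3 doubly deficient, against 1443 and 999 with a pseudocount of 0.1 FPKM. Sfrp1 (189 against 6.52 FPKM), 1500015O10Rik (56.0 against 1.65 FPKM), the granzyme Gzme (27.3 against 1.07 FPKM) and the kinase Dmpk (140 against 10.5 FPKM) were among the 5 largest higher differences, with the uncertain LOC100861572. Igfbp5 (18.5 against 470 FPKM), Tnnt2 (2.05 against 23.2 FPKM) and the uncertain Rps27, LOC100861570 and LOC100302567 were the 5 largest lower ones. Mitotic genes (-1.16, 22 of 27 lower) and G1/S genes (-1.11, 16 of 26 lower) stood apart as lower. Interferon-stimulated genes (0.66, 7 of 27 higher), senescence inhibitors and secretory genes (0.61, 4 of 21 higher and 1 lower, with Il6 at 4.77 against 0.87 FPKM), glycolysis and hypoxia genes (0.58, 5 of 20 higher and 1 lower) and p53 targets (0.19, with Fas alone past the rule at 7.86 against 3.29 FPKM) stood apart as higher. The telomere maintenance list stood apart in this comparison (-0.29) with none of 19 members past the rule. Histone genes (1.04, 4 of 7 higher), anterior Hox genes (0.57, 2 of 19 higher), contractile genes (0.52, 5 of 15 higher), imprinted genes (0.38, 3 of 18 higher and 2 lower) and collagen and matrix genes (0.20, though with 2 of 24 higher and 3 lower) also stood apart as higher, beside smooth muscle and pericyte markers (0.93, 3 of 6 higher, or 0.085 with a mean FPKM of at least 5). ATF4 and unfolded protein response genes (-0.75, 6 of 19 lower), cholesterol synthesis genes (-0.72), ribosomal protein genes (-0.41), DNA damage response genes (-0.39), heterochromatin genes (-0.37), immediate early genes (-0.33), base excision repair genes (-0.33) and oxidative phosphorylation genes (-0.28) stood apart as lower.

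Differences that share no library could be compared. Across 11589 genes the G3 Terc-deficient minus wild-type and the G3 doubly deficient minus Gadd45a-deficient differences had r = 0.66 and rho = 0.72. Of the 1282 genes higher in the first, 205 were among the 300 higher in the second, and 5 were lower. The 1282 genes had a median of 1.48 in the first comparison and 0.51 in the second. Of the 749 lower genes, 212 were among the 293 lower ones, and 2 were higher, with medians of -1.36 and -0.75. The Gadd45a-deficient minus wild-type and the G3 doubly deficient minus G3 Terc-deficient differences had r = -0.0092 and rho = -0.027. The 40 higher genes of the former shared 8 with the 191 of the latter and 4 were lower, and the 31 lower genes shared 4 with the 628 and 1 was higher. Independent sets of these sizes would share 17.1, 9.75, 0.34 and 0.87 genes, for the overlaps of 205, 212, 8 and 4. Those are drawn from all 22497 symbols, which include genes too low to pass the rule. The G3 Terc-deficient minus wild-type and the G3 doubly deficient minus G3 Terc-deficient differences had r = -0.76, but share a library. Permutation gave r = -0.50, a value fixed by making the 4 libraries alike in spread. A shared library that differs more than the others can give a stronger r, so the gap between these values shows no relation beyond it. Genes are not independent replicates, so these values describe the libraries.

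**Figure D3:**
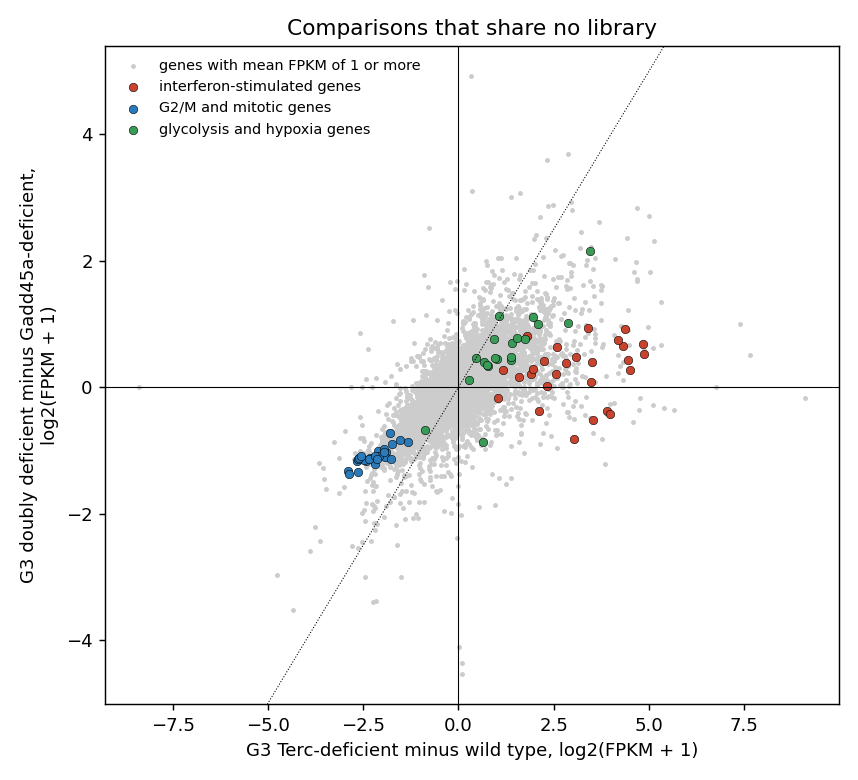
Each point is 1 of 11589 genes, with its difference of log2(FPKM + 1) between the libraries labelled G3 Terc-deficient and wild type on the x axis and between those labelled G3 doubly deficient and Gadd45a-deficient on the y axis, and a dotted line where both are equal. Mitotic genes lie low on both axes (medians -2.20 and -1.12), while interferon-stimulated genes lie far to the right and lower on the y axis (medians 3.09 and 0.28).

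The double difference asks whether the difference that goes with the Gadd45a label was larger in G3 cells than in Terc-proficient cells. It counted 254 genes higher and 771 lower (365 and 655 after quantile normalization, 1085 and 1937 with a pseudocount of 0.1 FPKM). Saa3 (-9.27), Ccl11 (-7.15), Lcn2 (-6.75), LOC100861572 (-6.39) and Cxcl1 (-6.03) had the most negative values, and LOC100861570 (8.40), Xist (4.61), Ptn (3.44), Tnmd (3.28) and H19 (2.98) the most positive. The values of both LOC symbols are uncertain, and Xist reflects the sex-linked transcripts of the library labelled Gadd45a-deficient. Interferon-stimulated genes had a median double difference of -2.61 with 25 of 27 lower, senescence inhibitors and secretory genes -1.90 with 13 of 21 lower and 1 higher, and mitotic genes 1.08 with 17 of 27 higher. No error can be given for these values.

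Erythroid, and pluripotency and germ cell, lists had 0 measured members, melanocyte markers 1, neural markers 2 and endothelial markers 2, too few for a median. Liver markers had a median of -1.29 in the library labelled Gadd45a-deficient minus wild type, set by Alb and Trf (0.19 against 1.90 FPKM), and epithelial markers -0.42, with Krt8 at 0.53 against 3.04 FPKM and Krt18 at 2.09 against 5.52 FPKM. The other 2 of the 4 measured epithelial markers were above 0 in this comparison. Mesothelial (-0.27), skeletal muscle (0.56), adipocyte (0.30) and smooth muscle and pericyte markers (0.22) also stood apart there. These lists have few measured members, and most marker lists that stood apart, over all comparisons, no longer did with a mean FPKM of at least 5. Part of that loss is not a change of median. Some lists, macrophage and leukocyte markers among them, then had fewer than 3 measured members and so no median. Beside the inflammatory genes of the library labelled G3 Terc-deficient, the 4 measured of 14 macrophage and leukocyte markers had a median of 0.70 over wild type that did not stand apart. All 4 were above 0, while 7 markers under the minimum mean FPKM, Tyrobp and C1qa among them, were lower than in wild type. When each library was rescaled to a sum of 1000000 the median was -0.14, with markers of low FPKM then counted as measured. Epithelial (-1.30, 3 of 4 lower), cartilage and bone (-1.19, 2 of 3 lower, with Sox9 at 2.62 against 7.29 FPKM) and smooth muscle and pericyte markers (-0.81, or -0.16 when rescaled in that way, 3 of 6 lower and 1 higher, with Cspg4 at 4.35 against 31.0 FPKM) stood apart as lower in the library labelled G3 Terc-deficient. Between the G3 libraries, smooth muscle and pericyte (1.45, 4 of 6 higher), cartilage and bone (0.86, none of 3 past the rule), mesothelial (0.85, 2 of 4 higher), epithelial (0.82, 2 of 4 higher) and adipocyte markers (0.38, none of 4 higher and 1 lower) stood apart as higher in the library labelled doubly deficient. In that library the macrophage gene Lyz2 stood at 11.5 FPKM against 2.1 in wild type, and leukocyte markers stood apart from wild type (0.92).

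Genes near the targeted loci and chromosome ends were compared as a check of carried-over sequence and of position. The 18 measured neighbours of Gadd45a had a median of -0.064 in the library labelled Gadd45a-deficient minus wild type, with none past the rule, and the 82 neighbours of Terc a median of 0.0018 in the library labelled G3 Terc-deficient minus wild type, with 11 higher and 3 lower. Neither stood apart in any comparison. The 535 genes near distal chromosome ends had medians of -0.021 between the libraries labelled G3 Terc-deficient and wild type and 0.026 between the G3 libraries. The latter stood apart as higher (percentile 99.9) with 12 genes higher and 21 lower, a shift far below the size rule.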

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

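All tests reported in this part were chosen after the results were seen.

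Some results differed in direction between the comparisons without and with the Terc label, and the difference was not tested, since each rests on single libraries. Between the libraries labelled Gadd45a-deficient and wild type, and then between those labelled G3 doubly deficient and G3 Terc-deficient, the medians were 0.22 and -1.74 for senescence inhibitors and secretory genes, 0.27 and -2.45 for interferon-stimulated genes, 0.14 and -0.66 for NRF2 antioxidant genes, 0.096 and -0.45 for glycolysis and hypoxia genes, -0.21 and 0.68 for cholesterol synthesis genes, -0.42 and 0.82 for epithelial markers and -0.27 and 0.85 for mesothelial markers. Both marker lists rest on 4 measured members. Between the libraries labelled Gadd45a-deficient and wild type 2 epithelial markers were above 0 and 2 below, and 1 mesothelial marker was above 0 and 3 below. Hoxb13, a posterior patterning gene, differed by -1.06 and 1.32, and Wisp2, a Wnt target, by 1.22 and -1.59. Between the libraries labelled G3 Terc-deficient and wild type, and then G3 doubly deficient and Gadd45a-deficient, Hoxd11 differed by 1.24 and -1.53 and Sema7a by -1.21 and 1.07.

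The Gadd45a transcript was not lower where the labels name its loss. If the allele removed the transcript, a swap of labels among the 4 libraries would leave 2 of them with little of it, but the lowest library held 0.51 of the FPKM of the highest, so such a swap cannot account for the values. Library scaling cannot either, since the difference from wild type was 0.58 after median-of-ratios rescaling. Transcript from parts of the gene left in the targeted allele could give such values, and cannot be told apart from a full transcript (difference 0.54), because there is 1 value per gene. A label error that involves an allele of that kind, or a culture from outside the series, was not tested.

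Interferon-stimulated genes were much higher than wild type in the library labelled G3 Terc-deficient (median 3.09) and less so in the libraries labelled G3 doubly deficient (0.66) and Gadd45a-deficient (0.27). Leukocytes in the culture would bring their abundant transcripts, but all 14 macrophage and leukocyte markers together stood only 4.30 FPKM above wild type, with Cd14 and Cd53 higher and Tyrobp and C1qa listed at 0, where the median interferon-stimulated gene stood 25.3 FPKM above it. In the library labelled G3 doubly deficient these markers stood 22 FPKM above wild type and the median interferon-stimulated gene 1.91 FPKM. This argues against leukocytes as the main source. Scaling cannot account for the difference, as the list median was 2.96 after quantile normalization. If cultures of 1 genotype were alike, the Terc genotype alone would bring the same difference with either Gadd45a label. Between the libraries labelled G3 doubly deficient and Gadd45a-deficient the median was 0.28. With 1 culture per genotype, and sex-linked transcripts that differ between these libraries, this cannot exclude the Terc genotype alone. The biological explanation that the design offers, an inflammatory state of G3 Terc-deficient cells that needs intact Gadd45a, cannot be told apart from the state of a single culture, such as its density, passage or a stimulus (median 3.09 with 1 library each), and Gadd45a itself was not lower in the libraries labelled deficient.

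The 71 genes past the size rule between the libraries labelled Gadd45a-deficient and wild type include 6 on X or Y, so sex-linked genes do not make up most of them. Genes listed at 0 in 1 of the libraries numbered 14, so these do not make up most of them either. No biological explanation was tested for these genes, and a difference between single cultures or embryos stays open.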

How the results depend on the processing

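The alternatives without X and Y genes and without genes listed at 0 were chosen after the data were seen; the others were planned. Of 145 values that answer a comparison under the alternatives, 110 stayed within the limit set for them and 35 moved, all 35 being counts. With a pseudocount of 0.1 FPKM, which lets genes of a few fragments pass the size rule, the counts of genes higher and lower were 372 and 447 for the libraries labelled Gadd45a-deficient minus wild type, 2705 and 1440 for G3 Terc-deficient minus wild type, 732 and 1624 for G3 doubly deficient minus G3 Terc-deficient, 1241 and 792 for G3 doubly deficient minus Gadd45a-deficient, 1443 and 999 for G3 doubly deficient minus wild type and 1085 and 1937 for the double difference. With a mean FPKM of at least 5, which leaves fewer genes, they were 23 and 10, 698 (higher only), 127 and 334, 176 and 191, 284 and 233, and 158 and 404 in the same order, and 4 marker lists in place of 24 stood apart over all comparisons. Some marker lists had fewer than 3 measured members there, so they had no median and could not stand apart. Quantile normalization gave 290 genes higher in the G3 doubly deficient minus G3 Terc-deficient comparison, and 2 positional lists in place of 1. Rescaling to a sum of 1000000, which also makes all values larger against the pseudocount and so does not test scaling alone, gave 85 higher and 67 lower for Gadd45a-deficient minus wild type, and 339, 538, 762 and 455 higher for the last 4 comparisons in that order. Keeping short RNA gave 96 and 84 for Gadd45a-deficient minus wild type, and leaving out genes listed at 0 gave 18 lower.

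Of 1212 list values, 1154 were the same, 29 came to stand apart, 27 no longer did and, counting only lists that stood apart and judged by their percentile, 2 reversed: senescence inhibitors and secretory genes (0.20, and -0.012 rescaled to a sum of 1000000) and smooth muscle and pericyte markers (0.64, and -0.099 with a mean FPKM of at least 5), both between G3 doubly deficient and Gadd45a-deficient. With a mean FPKM of at least 5 the values are unchanged and only the measured members differ. Rescaling applies the minimum to larger values, so members can enter, and also shifts values against the pseudocount. Which of these gave the other reversal was not tested. Of the 27 list values that no longer stood apart, 12 came with a mean FPKM of at least 5 and 6 with rescaling to a sum of 1000000. Lists left with fewer than 3 measured members had no value and are not counted among the 27. Quantile normalization gave 5 and a pseudocount of 0.1 FPKM 4. Of 2933 values of named genes 2776 were the same, 157 moved and, of those past the size rule, 0 reversed. Keeping the highest line of a repeated symbol changes nothing, since every symbol stands on 1 line. No paired analysis was possible because the labels give no replicate numbers and no test was run. Depth limits genes of a few fragments, Terc among them.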

Other observations

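The gene sets in this part were chosen after their values were seen. Of 16 measured genes of antigen presentation on MHC class I 13 were higher in the library labelled G3 Terc-deficient than in wild type, with a median difference of 2.79, and 13 were lower in the library labelled G3 doubly deficient than in the library labelled G3 Terc-deficient, with a median of -2.49. They did not stand apart between the libraries labelled G3 doubly deficient and wild type (0.096). In the order wild type, Gadd45a-deficient, G3 Terc-deficient and G3 doubly deficient, B2m, the light chain of class I molecules, stood at 298, 381, 2267 and 394 FPKM, H2-K1 at 35.3, 35.7, 399 and 25.1 FPKM and the immunoproteasome subunit Psmb8 at 2.51, 5.94, 46.8 and 2.95 FPKM. Psmb10 was an exception at 13.3, 12.5, 11.1 and 11.5 FPKM.

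Complement and acute-phase genes were also highest in the library labelled G3 Terc-deficient, with 10 of 10 measured members higher in the library labelled G3 Terc-deficient than in wild type (median 4.39) and 10 of 10 lower in the library labelled G3 doubly deficient than there (median -2.87). The latter remained above wild type (0.44, 4 of 10 higher) and above the library labelled Gadd45a-deficient (0.70, 2 of 10 higher). Serping1, the C1 inhibitor, stood at 5.74, 6.66, 70.1 and 12.9 FPKM and ceruloplasmin, Cp, at 0.43, 0.29, 36.0 and 3.13 FPKM. Some leukocyte transcripts were highest in the library labelled G3 doubly deficient, with C1qa at 0.29, 0.85, 0 and 2.17 FPKM and Tyrobp at 0.28, 0.28, 0 and 1.52 FPKM. The 4 measured macrophage and leukocyte markers fixed in advance had a median of -0.0044 between the G3 libraries, with 2 above 0 and 2 below. With each library rescaled to a sum of 1000000 the median was 1.77, but over a larger set. Markers of low FPKM such as C1qa then passed the minimum mean FPKM.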
